A study of Arabidopsis thaliana with 12 samples.

How the data were processed

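Gene expression was measured with Affymetrix ATH1 arrays in leaves of Arabidopsis thaliana. Per the labels' protocols, plants were 2 weeks old, grown at 23 °C by day and 18 °C by night with 16 h of light and 8 h of dark, and chilled at 4 °C. Each plate held at least 30 seedlings, and RNA with an integrity number of at least 7.5 was used. The 12 arrays fall into 6 groups of 2: wild type (WT) and the rdm4 mutant, each after 0, 3 and 48 h of chilling. RDM4 is a protein associated with RNA polymerase II that acts in RNA-directed DNA methylation. Groups and replicate numbers were taken from the sample titles, and the source names give the same genotype, time and replicate number. On other points labels conflict with the titles. The titles name the accession C24 for the wild type where the source names and the ecotype field have Col, the genotype field of the mutant arrays names an RDM4 overexpression construct, and the free-text descriptions of the replicate 2 arrays name other treatments than their titles. Per the labels, replicates came from different growth chambers, but no label says that a replicate number marks the same chamber in different groups.

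The deposited values were on a log2 scale, as found from their range, with array medians from 6.34 to 6.43. The summarisation and normalization method that the authors used is not given in the sources used here. The deposited log2 values were used without further normalization. Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. The platform annotation used here paired 13513 of these with 1 gene and 503 with several genes, and 8730 probe sets have no entry in it and stay unnamed here. Probe sets with several genes were given no name. The named probe sets covered 13355 genes, of which 13286 were matched by gene number to a RefSeq gene table that gave current symbols, and 11808 carry a locus tag as their only name. For the 147 genes with more than 1 probe set, 1 probe set stood for the gene, and other probe sets were compared where the gene is named. Probe sets of near-identical genes can read more than 1 copy, so values of PDF1.2b and AT4G10580 are uncertain in that respect.

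Each comparison was fitted with limma 3.58.1 in R 4.3.3 as a model of 6 group means over all 12 arrays (lmFit and eBayes, 6 residual and 5.97 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within a comparison, and an adjusted p under 0.05 was a call. Changes are given as log2 differences ± SE, with 2 arrays per group throughout. The comparisons were 3 h and 48 h against 0 h in each genotype, rdm4 against WT at each time, and the difference between the genotypes' responses at 3 h and at 48 h. The mean of both genotypes' responses was added after the data were seen, because at 3 h it does not depend on which arrays carry which genotype label. The number of arrays limits the precision. Background was not measured, so a change that starts or ends among the dimmest 30% of a group's probe sets is of uncertain size. At such a level in WT were AT1G17960, AT1G52070, AT3G01830, CML37, EXPA7, M17, NRPC1, RSU1, XTH18, XTH19 and XTH20 at 0 h, AT1G66090, AT3G01830, AT5G59670, ATHSP22.0, CML37 and WRKY53 at 3 h, and AT1G17960, AT3G01830, CML37, EXPA7, NRPC1, PUB24, RSU1 and WRKY53 at 48 h. In rdm4 these were AT1G66090, AT3G01830, AT5G52760, CML37, EXPA7, HYH, WRKY53, XTH18 and XTH20 at 0 h, and AT1G17960, AT1G66090, AT3G01830, CML37, EXPA7, NRPC1, RSU1 and WRKY53 at 3 h. The size of every change, difference or mean that uses one of these levels is uncertain.

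Before the data were examined, 20 gene lists with 281 members were fixed. The annotation named 34 of these members, and 4 lists had at least 3: cold-regulated (COR) effector genes, light harvesting and photosynthesis, root markers, and reference genes. Another 38 sets were formed once the annotation had been seen and before any test: families of at least 6 genes whose symbols share a stem, and the plastid-encoded genes. A shared stem does not show that genes are related, so a list such as the PDF family can mix unrelated genes. The 42 lists were tested in 11 contrasts with camera at a preset correlation of 0.01, adjusted over all 462 tests. Of 41 calls, 0 held when the correlation was estimated from the data, and the adjusted p with that estimate is given beside each call. The estimate rests on 6 residual degrees of freedom, and its power was not tested. A call lost with it therefore does not show that the list was unchanged. The rotation test fry was also run, and it asks only whether a list's genes moved one way on balance.

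Genes are named by a rule fixed before the data were examined. It takes RDM4, CBF1 to CBF3, COR15A, COR15B, RD29A, KIN1 and KIN2 wherever measured, of which the annotation used here named only COR15A and COR15B. It takes up to 4 members of a described list with the largest called changes and up to 2 that were not called. It also takes up to 10 rises and 10 falls per comparison, or 5 of each for differences of responses, among called genes whose arrays did not overlap between the groups. Any other gene is said to be chosen after its values were seen.

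The scripts were tested on simulated arrays with 200 of 22746 probe sets changed in 1 group. In the simulated comparison of rdm4 at 48 h with 0 h, 100% of changes of 1 and of 2 on the log2 scale were recovered, 70% of changes of 0.5 and 14% of changes of 0.3, with 6 unchanged probe sets among 148 calls. In the simulated difference of the 48 h responses these shares were 94%, 100%, 42% and 0% for changes of 1, 2, 0.5 and 0.3. Far more probe sets were called in the data, such as 6787 for rdm4 against WT at 0 h. The adjusted p depends on that number, so these shares do not give the sensitivity in the data. The alternatives tried were a repeated quantile normalization, centring each array on its median, leaving out the dimmest 30% of probe sets, eBayes with trend and robust estimation, fits on the arrays of the compared groups, a replicate block, a 2-fold minimum, the mean of a gene's probe sets, and leaving out each array in turn. Leaving out all 3 h arrays was added after the data were seen. Figures were drawn with matplotlib 3.10.9.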

Results

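The data were 12 arrays of leaf RNA from Arabidopsis WT and rdm4 plants, 2 per genotype after 0, 3 and 48 h at 4 °C. Replicate arrays correlated across probe sets with r from 0.997 to 0.999, and the SD of their log2 difference was 0.13 to 0.17. The design asks which transcripts respond to chilling, and how far this depends on RDM4. Unchilled plants were sampled at 0 h only. A change at 3 h therefore cannot be told apart from one of time of day or age. As 48 h is a whole number of days, a change there is open to one of age. Time of day stays open at 48 h if the clock time of sampling differed from that at 0 h. In controls for RNA integrity, the 3′ minus 5′ log2 signal of GAPDH was 0.92 ± 0.08 (SD, n = 2) in WT at 0 h, 0.67 ± 0.07 at 3 h and 0.54 ± 0.03 at 48 h. In rdm4 it was 0.72 ± 0.11, 0.79 ± 0.05 and 0.57 ± 0.05 at these times. That of actin was 0.47 ± 0.11, 0.57 ± 0.06 and 0.61 ± 0.02 in WT and 0.41 ± 0.08, 0.51 ± 0.06 and 0.61 ± 0.05 in rdm4. That of ubiquitin was 1.06 ± 0.05, 1.03 ± 0.01 and 1.03 ± 0.02 in WT and 1.05 ± 0.02, 1.00 ± 0.01 and 1.05 ± 0.06 in rdm4.

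The difference between the genotypes changed sign at 3 h. NRPC1, the largest subunit of RNA polymerase III, had log2 levels of 4.46 ± 0.05 in WT and 6.23 ± 0.08 in rdm4 at 0 h (SD, n = 2), 6.16 ± 0.05 and 4.31 ± 0.21 at 3 h, and 4.34 ± 0.03 and 6.05 ± 0.06 at 48 h. RSU1 went the same way, at 1.67 higher in rdm4 at 0 h, -1.59 at 3 h and 1.82 at 48 h. The lower levels of both lay among the dimmest 30% of probe sets, and both were chosen after their values were seen. Of 81 probe sets called in the same direction at 0 h and 48 h with at least 2-fold at both, 75 were called at 3 h, 73 in the opposite direction and 2 in the same. Only 11 probe sets were called in this way at 0 h and 3 h, and 7 of the 8 called at 48 h were opposite there. For 3 h and 48 h there were 15, and 13 of the 14 called at 0 h were opposite there. With no minimum size, 3094 probe sets were called in the same direction at 0 h and 48 h against 1181 for independent lists, 339 at 0 h and 3 h against 1243, and 1002 at 3 h and 48 h against 1470. Of those called at the third time as well, 97.0% of 2337 were opposite at 3 h, 69.1% of 230 at 48 h and 86.1% of 512 at 0 h. The 3′ minus 5′ signal of GAPDH was also lower in rdm4 than in WT at 0 h, by -0.20, and higher at 3 h, by 0.12, and the difference was 0.03 at 48 h. For actin it was -0.06, -0.07 and -0.005, and for ubiquitin -0.01, -0.03 and 0.02; these differences were not tested. Across all probe sets the log2 differences at 0 h and 3 h, which share no arrays, correlated with r = -0.61, those at 3 h and 48 h with r = -0.36 and those at 0 h and 48 h with r = 0.22, where probe sets are not independent replicates. The RDM4 transcript itself was not analysed here, so it gives no check of the labels. The groups below are therefore the arrays labelled WT and rdm4.

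**Figure D1:**
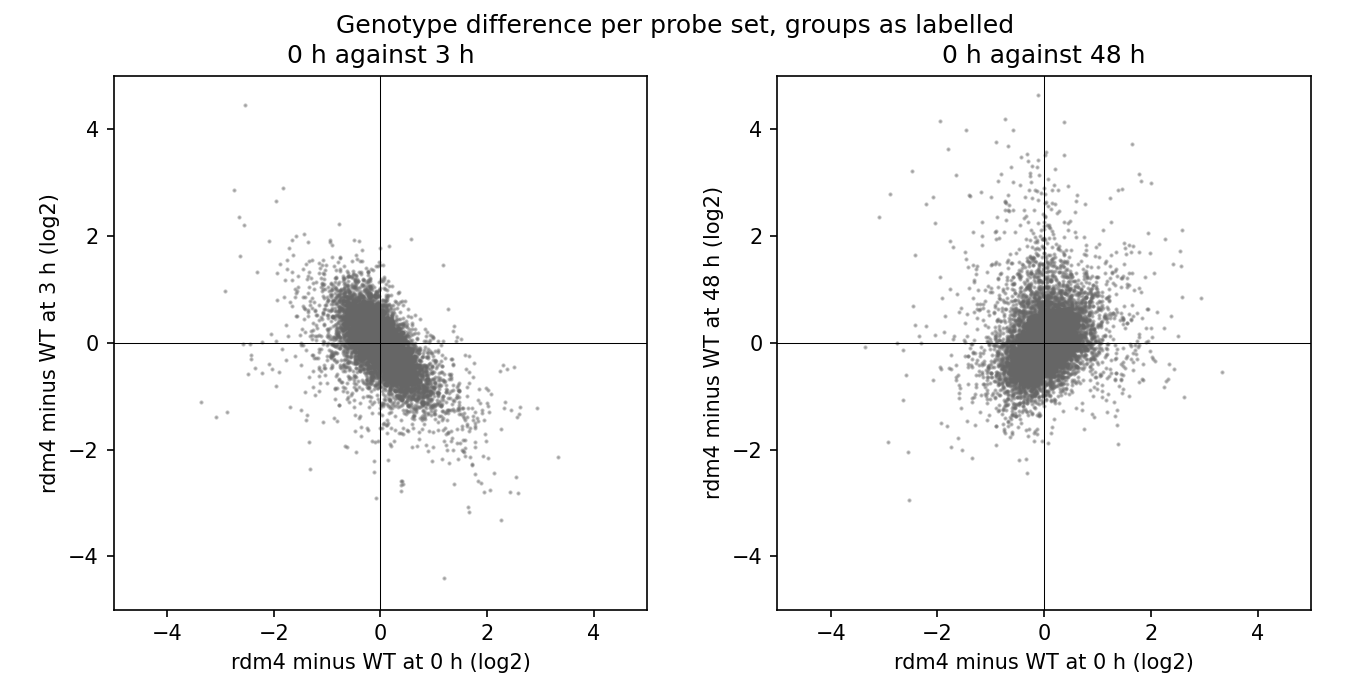
The log2 difference of rdm4 minus WT at 0 h (horizontal axis) is set against that at 3 h (left) and 48 h (right), 1 point per probe set, each from 2 arrays per group. The points slope downward at 3 h (r = -0.61) and weakly upward at 48 h (r = 0.22).

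After 3 h of chilling, all 6 named cold-regulated (COR) genes were called higher in the mean of both genotypes, with a median log2 change of 1.31, and 3 of them were called higher in each genotype. LTI30 and COR47, which encode dehydrins, rose by 3.01 ± 0.06 (adjusted p = 1.33e-12) and 1.53 ± 0.05, and COR15A and COR15B, which encode cryoprotective proteins of the chloroplast stroma, rose by 1.08 ± 0.06 and 1.00 ± 0.05. The means of COR15A, COR15B and COR27 rest on the arrays labelled rdm4, where they were at 2.39, 1.89 and 1.36, against -0.23, 0.10 and -0.04 in those labelled WT. All 6 were also called when adjusted over the list alone. In every comparison the counts of COR genes and root markers adjusted over the list alone equalled those over all genes, except for 3 in place of 2 COR genes in the difference of the 48 h responses. Against other genes the COR list was called (camera, adjusted p = 6.17e-08), and had an adjusted p = 0.351 with an estimated correlation.

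The largest mean rises of named genes at 3 h were AT3G55580 at 3.90 ± 0.07, AT4G36010 at 3.47 ± 0.06 and AT1G73480 at 3.19 ± 0.05. AT5G65300, AT1G70420, HYH, AT3G04010, AT3G51660 and AT5G48540 rose by 2.65 to 3.17. HYH encodes a bZIP factor related to HY5, and the size of its rise is uncertain because of its dim level in rdm4 at 0 h. The zinc finger factor gene STZ rose by 1.65 ± 0.05 and the clock gene GI by 0.92 ± 0.05. The largest falls of named genes were AT3G26510 at -3.95 ± 0.07, AT1G23390 at -3.69 ± 0.07, AT3G23880 at -3.69 ± 0.07 and AT5G19120 at -3.66 ± 0.06.

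Among symbol families, 8 of 8 autophagy genes of the ATG family were called lower at 3 h in the mean of both genotypes, among them ATG8E at -1.01 ± 0.08 and ATG8F at -0.52 ± 0.05 (camera, adjusted p = 0.00661, and adjusted p = 0.608 with an estimated correlation). Of the 8, 4 were called lower in each genotype and 1, ATG3, in neither (adjusted p = 0.077 in WT and 0.30 in rdm4). The means of the other three rest on the arrays labelled rdm4, with ATG8B at -1.02, ATG8G at -0.45 and ATG8H at -0.64, against 0.23, 0.01 and 0.01 in those labelled WT. In the XTH family, whose enzymes remodel xyloglucan in the cell wall, 5 of 9 rose and 0 fell, led by XTH19 at 2.60 and XTH18 at 1.68 (adjusted p = 3.78e-04, and adjusted p = 0.351 with an estimated correlation). These 2 means rest on the arrays labelled WT, with 5.20 for XTH19 and 3.26 for XTH18, both from dim levels at 0 h, so that their sizes are uncertain. In those labelled rdm4 XTH19 was at 7.01 at both times and XTH18 at a change of 0.10 ± 0.13, and neither was called. Of 14 SWEET sugar transporter genes the means of 7 were called higher and of 0 lower, with SWEET13 at 2.44 ± 0.06 (adjusted p = 0.0290, and adjusted p = 0.439 with an estimated correlation). Of the 7, 3 were called higher in each genotype and 2 were called in opposite directions, SWEET1 at 1.70 in WT and -1.33 in rdm4, and SWEET4 at -0.81 and 1.49. In the UGT family of glycosyltransferases the means of 19 of 47 were called higher and of 10 lower (adjusted p = 0.0115, and adjusted p = 0.351 with an estimated correlation), of which 7 and 4 were so called in each genotype. In the PDF family the means of 4 of 7 were called higher and of 1 lower (adjusted p = 0.0402, and adjusted p = 0.439 with an estimated correlation), a call that ended after repeated quantile normalization, without the dimmest 30% of probe sets, and without WT 0 h replicate 1 (adjusted p = 0.0501), WT 3 h replicate 1 (0.0650) or rdm4 3 h replicate 2 (0.0538), over a range of 0.0301 to 0.152. Only 1 of these 5 was called in the same direction in each genotype. PDF1.2b at -3.09 in WT and 3.91 in rdm4, PDF1.2 at -0.56 and 0.96, and PDF1A at 0.23 and -0.49 were called in opposite directions, and PDF2.1 was at 2.87 and 0.02. The ATG, SWEET and PDF genes given by genotype here were chosen after their values were seen. The 3 named root markers, AT5G17820, PYK10 and EXPA7, also rose over the same arrays, with a median of 0.91 (adjusted p = 0.00387, and adjusted p = 0.351 with an estimated correlation). Their means too rest on the arrays labelled WT, and none was called in those labelled rdm4. In all, 9668 probe sets were called in the mean 3 h response, 613 at least 2-fold higher and 262 at least 2-fold lower.

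In the arrays labelled WT, XTH19 rose by 5.20 ± 0.11 at 3 h (adjusted p = 1.28e-11), EXLA1, an expansin-like gene, by 3.64 ± 0.08 and AT4G30170 by 3.63 ± 0.10. AT5G65300, AT1G52070, AT1G49220, AT4G36010, AT4G11190, AT5G05600 and AT1G17960 rose by 3.31 to 3.75. The sizes for XTH19, AT1G52070 and AT1G17960 are uncertain because of their dim levels at 0 h. The root markers AT5G17820 and PYK10 rose over the same arrays, by 3.28 ± 0.08 and 1.89 ± 0.06, and the list's median was 1.89 with all 3 called (adjusted p = 0.00198, and adjusted p = 0.351 with an estimated correlation). AT3G23880 fell by 4.52 ± 0.10, and AT1G23390 by 4.39 ± 0.10. PDF1.2b, a defensin gene, was lower at -3.09 ± 0.15 and ORA47, an ERF factor gene, at -2.66 ± 0.12. Of the 6 COR genes 3 rose, COR47, LTI30 and AT4G33980, and 1 fell, COR15A at -0.23 ± 0.08 (adjusted p = 0.0266). COR15B was at 0.10 ± 0.07 (adjusted p = 0.233), and was called with trend and robust estimation in eBayes (adjusted p = 0.0475). The COR15A call was lost without WT 0 h replicate 1 (-0.15, adjusted p = 0.212) or WT 3 h replicate 1 (-0.16, adjusted p = 0.194), and in a fit of the compared arrays alone, over a range of adjusted p from 3.04e-04 to 0.212. The COR list was not called (adjusted p = 0.0719).

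Several families moved in WT at 3 h. All 6 genes of the NRPB family, subunits of RNA polymerase II and related enzymes, rose, with a median of 0.61 (adjusted p = 0.00520, and adjusted p = 0.455 with an estimated correlation). In the GSTU family of glutathione transferases 8 of 11 rose and 1 fell, with GSTU22 at 1.59 ± 0.07 (adjusted p = 0.00988, and adjusted p = 0.351 with an estimated correlation), a call lost when the dimmest 30% of probe sets were left out. In the XTH family 7 of 9 rose (adjusted p = 0.00143, and adjusted p = 0.351 with an estimated correlation), and in the UGT family 20 of 47 rose and 7 fell (adjusted p = 0.0165, and adjusted p = 0.351 with an estimated correlation). In total 10644 probe sets were called, 5250 higher and 5394 lower, and centring each array on its median gave 4826 higher and 6312 lower. At least 2-fold, 1008 were higher and 581 lower.

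In the arrays labelled rdm4, all 6 COR genes rose at 3 h, with a median of 2.14. LTI30 rose by 3.73 ± 0.08 (adjusted p = 1.11e-11), AT4G33980 by 2.50 ± 0.07 and COR15A by 2.39 ± 0.08 (list, adjusted p = 5.30e-09, and adjusted p = 0.351 with an estimated correlation). AT3G55580 rose by 4.65 ± 0.10, AT1G73480 by 4.04 ± 0.07, PDF1.2b by 3.91 ± 0.15 and AT3G51660 by 3.91 ± 0.09. AT3G26510 fell by 3.69 ± 0.09, AT5G19120 by 3.66 ± 0.09 and M17 by 2.75 ± 0.11. In the PDF family 5 of 7 rose and 1 fell (adjusted p = 0.0184, and adjusted p = 0.421 with an estimated correlation), a call lost when the dimmest 30% of probe sets were left out, and in the ATG family 7 of 8 fell (adjusted p = 0.00383, and adjusted p = 0.592 with an estimated correlation). The root markers AT5G17820 and PYK10 were at -0.04 ± 0.08 and -0.07 ± 0.06 and were not called. In total 9102 probe sets were called, 3887 higher and 5215 lower, while at least 2-fold 735 were higher and 447 lower. Across probe sets the 3 h responses of WT and rdm4, which share no arrays, correlated with r = 0.26 and rho = 0.07. In both, 3334 probe sets were called in the same direction, against 2134 for independent lists, and 2740 in opposite directions, against 2125.

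After 48 h of chilling, HYH rose by 4.42 ± 0.10 in WT (adjusted p = 4.39e-12) and by 6.31 ± 0.10 in rdm4 (adjusted p = 2.87e-13). SWEET13, a sucrose transporter gene, rose by 4.39 ± 0.09 and 4.23 ± 0.09, AT3G55580 by 3.69 ± 0.10 and 4.57 ± 0.10, and LTI30 by 3.62 ± 0.08 and 3.95 ± 0.08. In WT the chalcone isomerase-like gene CHIL rose by 3.58 ± 0.10 and XTH20 by 3.26 ± 0.09. In rdm4, AT5G52760 rose by 5.10 ± 0.14, XTH18 by 5.07 ± 0.13 and AT1G19020 by 4.99 ± 0.07. Dim levels at 0 h make the sizes uncertain for XTH20 in WT and for HYH, AT5G52760 and XTH18 in rdm4. AT5G19120 fell by 5.05 ± 0.09 in WT and 4.46 ± 0.09 in rdm4, AT1G23390 by 4.72 ± 0.10 and 5.20 ± 0.10, and the expansin gene EXPA8 by 4.40 ± 0.15 and 4.24 ± 0.15.

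Of the 6 COR genes, 4 rose in WT at 48 h and 2 fell, COR27 at -0.23 ± 0.07 and AT4G33980 at -0.32 ± 0.07 (list, adjusted p = 0.0515). In rdm4 4 rose and 1 fell (adjusted p = 0.0167, and adjusted p = 0.526 with an estimated correlation), with COR15A up by 2.59 ± 0.08 against 1.68 ± 0.08 in WT. The rdm4 calls of the COR list and of the ATG family below ended when the dimmest 30% of probe sets were left out, although the list medians were then still 1.74 and -0.76. COR15A had reached 14.06 ± 0.00 in WT at 48 h (SD, n = 2), near the highest values on the arrays, 14.46. In the ATG family 7 of 8 fell in WT and 7 of 8 in rdm4, and ATG8E fell by 2.91 ± 0.11 and 2.99 ± 0.11. The list was called in WT (adjusted p = 0.00310) and in rdm4 (adjusted p = 0.00520), both with adjusted p = 0.592 with an estimated correlation. The XTH family was called in rdm4, with 5 of 9 called higher (adjusted p = 0.00739, and adjusted p = 0.427 with an estimated correlation). Anthocyanin synthesis genes DFR and UF3GT rose by 1.19 ± 0.10 and 0.98 ± 0.07 in WT and by 0.83 ± 0.10 and 1.17 ± 0.07 in rdm4.

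The named genes of the light harvesting and photosynthesis list, LHCB4.1, LHCB4.2 and RCA, were lower at 48 h without a list call. In WT 3 of 3 fell, LHCB4.2 by 1.11 ± 0.07, and in rdm4 2 of 3 fell, LHCB4.2 by 1.77 ± 0.07; the list was not called (adjusted p = 0.178 and 0.235). Of 69 plastid-encoded genes 23 fell and 2 rose in WT (adjusted p = 0.0146, and adjusted p = 0.941 with an estimated correlation). That call ended without the dimmest 30% of probe sets, without WT 0 h replicate 2 (median -0.13, adjusted p = 0.282) or without WT 48 h replicate 2 (median -0.20, adjusted p = 0.173), over a range of adjusted p from 2.19e-04 to 0.282. In WT all 3 root markers rose (median 1.01, adjusted p = 0.0273, and adjusted p = 0.427 with an estimated correlation), while in rdm4 AT5G17820 rose by 0.63 ± 0.08 and PYK10 fell by 0.35 ± 0.06. Among reference genes PEX4 rose by 0.39 ± 0.07 in WT and 0.41 ± 0.07 in rdm4, and the list was not called in any comparison. Its median and mean differed in sign in rdm4 at 48 h (-0.05 and 0.06) and at 3 h (-0.01 and 0.04), in the mean 3 h response (-0.08 and 0.05) and in the difference of the 3 h responses (0.12 and -0.02). Those of the light harvesting and photosynthesis list did so in the difference of the 48 h responses (0.02 and -0.16). The calls numbered 11459 in WT and 11494 in rdm4. Across probe sets the 2 responses correlated with r = 0.78 and rho = 0.75. In the same direction 8515 probe sets were called, against 2902 for independent lists, and in opposite directions 440, against 2888.

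Averaged over both genotypes, HYH rose by 5.36 ± 0.07 at 48 h, SWEET13 by 4.31 ± 0.06 and LTI30 by 3.79 ± 0.06. The XTH family had 5 of 9 genes called higher (adjusted p = 0.0261, and adjusted p = 0.471 with an estimated correlation), 4 of them in each genotype, and the ATG family 6 of 8 called lower, all 6 in each genotype (adjusted p = 0.00387, and adjusted p = 0.592 with an estimated correlation). The means of 30 plastid-encoded genes were called lower and of 3 higher (adjusted p = 0.0125, and adjusted p = 0.934 with an estimated correlation), of which 15 and 2 were so called in each genotype. This last list call ended without the dimmest 30% of probe sets and without rdm4 0 h replicate 1 (median -0.19), WT 0 h replicate 2 (-0.23), WT 48 h replicate 2 (-0.25) or rdm4 48 h replicate 2 (-0.21), with adjusted p from 3.80e-04 to 0.120. In total 13122 probe sets were called.

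**Figure D2:**
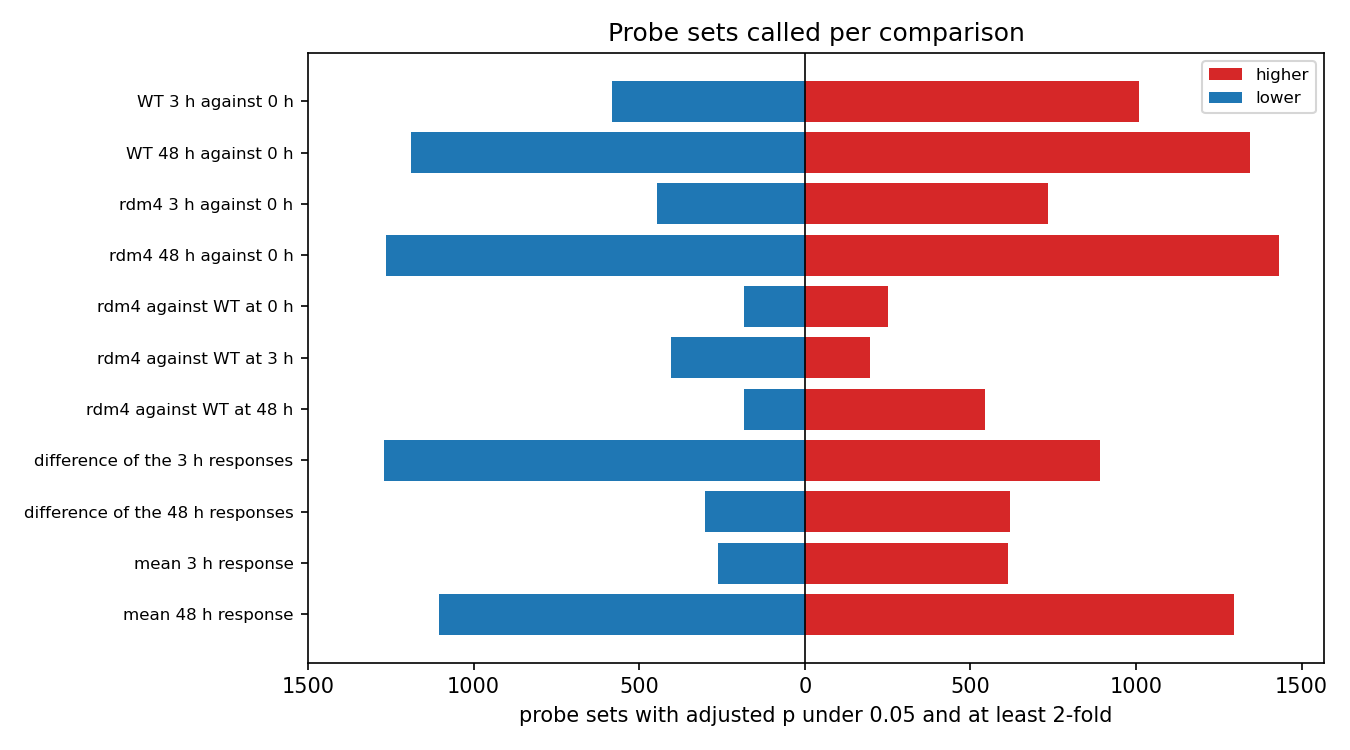
Bars give the number of probe sets with an adjusted p under 0.05 and at least 2-fold change, higher to the right (red) and lower to the left (blue), for each comparison and for the mean responses. The 48 h responses hold 2533 such probe sets in WT and 2698 in rdm4, and the genotype comparison at 0 h holds 434.

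Without chilling, COR transcripts were lower in rdm4 arrays than in WT. Of the 6 COR genes 5 were lower, COR15A by -1.36 ± 0.08 (adjusted p = 1.36e-07) and COR15B by -0.81 ± 0.07, with a list median of -0.58 (adjusted p = 0.00190, and adjusted p = 0.427 with an estimated correlation). AT1G78450 was lower by -2.64 ± 0.11, PDF1.2b by -2.54 ± 0.15, AT4G27280 by -2.48 ± 0.07, ORA47 by -2.05 ± 0.12 and STZ by -2.04 ± 0.07. AT4G23680 was higher in rdm4 by 2.58 ± 0.08 and PDF2.1 by 2.37 ± 0.10. M17 and XTH19 were called higher too, by 3.33 ± 0.11 (adjusted p = 2.26e-09) and 2.42 ± 0.11, sizes that are uncertain because of their dim levels in WT. The 3 root markers were higher over the same arrays, PYK10 by 1.32 ± 0.06 and AT5G17820 by 1.77 ± 0.08 (list, adjusted p = 0.00132, and adjusted p = 0.351 with an estimated correlation).

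In the NRPB family 5 of 6 genes were called higher in rdm4 at 0 h, NRPB9A by 0.90 ± 0.10 and NRPB12 by 0.48 ± 0.08 (adjusted p = 0.00831, and adjusted p = 0.471 with an estimated correlation), a call lost when the dimmest 30% of probe sets were left out. Plastid-encoded genes were called lower as a list (median -0.24, adjusted p = 0.0122, and adjusted p = 0.934 with an estimated correlation), although only 6 of 69 were called singly. That list had a median of 0.07 without rdm4 0 h replicate 2 and of -0.0005 without WT 0 h replicate 2, and its call ended in both fits. It ended too without the dimmest 30% of probe sets (median -0.25, camera, adjusted p = 0.0587). In total 6787 probe sets were called at 0 h, 3664 higher and 3123 lower, of which 251 and 183 were at least 2-fold.

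At 3 h, arrays labelled rdm4 had more of all 6 COR transcripts than those labelled WT, COR15A by 1.26 ± 0.08 (adjusted p = 2.06e-07), COR27 by 1.07 ± 0.07 and AT4G33980 by 1.05 ± 0.07. The list median was 1.02 (adjusted p = 1.01e-05, and adjusted p = 0.351 with an estimated correlation). PDF1.2b was higher by 4.46 ± 0.15, AT1G31690 by 2.20 ± 0.08 (1.39 on its other probe set) and AT5G55450 by 1.93 ± 0.07. AT2G27420 was lower by -2.91 ± 0.10, AT4G23680 by -2.81 ± 0.08 and XTH19 by -2.79 ± 0.11. AT1G17960 was called lower too, at -3.32 ± 0.12, but stood at 4.45 in rdm4, where 25.8% of probe sets were dimmer, so the size is uncertain. PDF1.2b, AT1G31690, AT4G23680 and XTH19 had the opposite sign at 0 h. Root markers were lower over these arrays (median -0.64, adjusted p = 0.00739, and adjusted p = 0.351 with an estimated correlation).

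The NRPB, XTH and GSTU families were lower in rdm4 at 3 h, with 5 of 6, 5 of 9 and 7 of 11 genes called lower. Their adjusted p-values were 0.00404, 0.0261 and 0.0276, and with an estimated correlation the adjusted p = 0.439, 0.471 and 0.427. The GSTU call ended without the dimmest 30% of probe sets or without WT 3 h replicate 2 (median -0.28, adjusted p = 0.0578), over a range of 0.0189 to 0.0993. The calls numbered 8357, with 4007 higher and 4350 lower, and centring each array on its median gave 5426 higher and 3653 lower. At least 2-fold, 196 probe sets were higher and 403 lower.

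After 48 h of chilling, CML transcripts were higher in rdm4 than in WT. In this family of calmodulin-like proteins 5 of 7 were called higher, CML37 by 2.85 ± 0.07 and CML41 by 1.61 ± 0.08 (list, adjusted p = 1.64e-04, and adjusted p = 0.351 with an estimated correlation). AT1G66090 was higher by 4.19 ± 0.09 (adjusted p = 2.75e-11), XTH18 by 4.13 ± 0.13, AT2G32030 by 3.98 ± 0.09 and AT5G52760 by 3.98 ± 0.14. STZ was higher by 2.24 ± 0.07 and SAG101, which acts with EDS1 in salicylic acid defence, by 0.95 ± 0.08. AT3G01830 was called higher too, by 4.64 ± 0.12, but stood at 3.73 in WT, where 8.0% of probe sets were dimmer. CML37 stood at 3.72 in WT, where 7.8% were dimmer. Background was not measured, so the sizes of these 2 differences are uncertain. PDF1.2b was lower by -2.95 ± 0.15, AT3G62550 by -2.44 ± 0.06 and AT3G07310 by -2.20 ± 0.09.

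Of the 6 COR genes, 4 were lower in rdm4 at 48 h, COR15A by -0.45 ± 0.08 and COR15B by -0.42 ± 0.07, and COR47 was higher by 0.36 ± 0.07; the list was not called (adjusted p = 0.127). Of the root markers EXPA7 was called higher, by 0.25 ± 0.08 from a dim level in WT, and PYK10 was at -0.05 ± 0.06 (list, adjusted p = 0.743). Calls numbered 7971, with 3640 higher and 4331 lower in rdm4, while at least 2-fold 545 were higher and 184 lower.

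**Figure D3:**
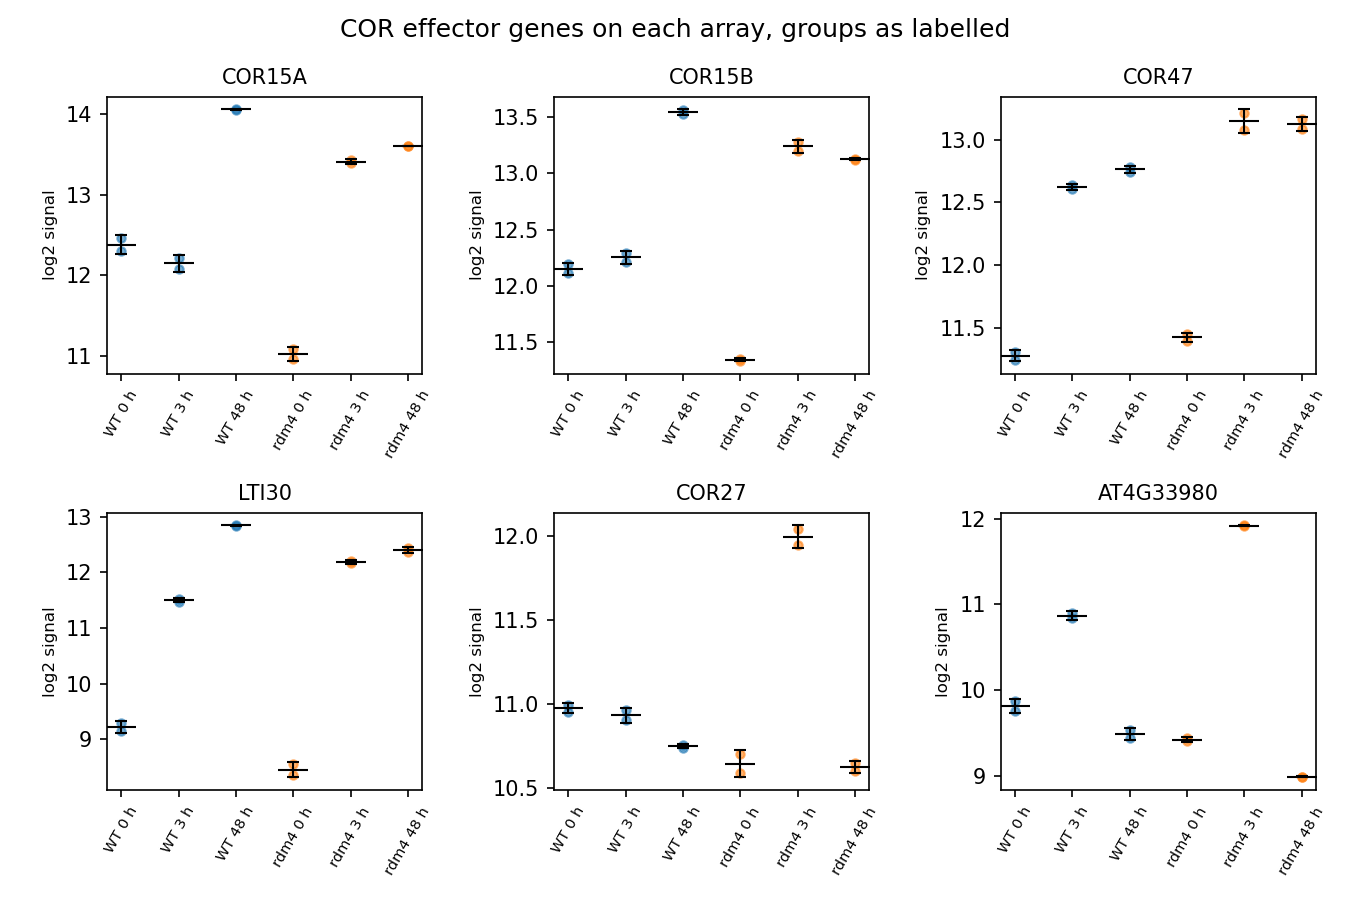
Log2 signal of the 6 named COR genes on each array (points, blue WT and orange rdm4) with the mean and SD of 2 arrays (black), in groups as labelled. COR15A lies at 12.38 in WT and 11.02 in rdm4 at 0 h, at 12.14 and 13.41 at 3 h, and at 14.06 and 13.60 at 48 h.

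The responses of the genotypes were then compared directly. At 3 h the COR list rose more in arrays labelled rdm4, with all 6 genes called and a median difference of 1.45, COR15A at 2.62 ± 0.11 (list, adjusted p = 6.14e-05, and adjusted p = 0.351 with an estimated correlation). By the probe set that stood for each gene, the differences of PDF1.2b at 6.999 ± 0.21 and AT1G31690 at 4.75 ± 0.12 were the largest above 0. The other probe set of AT1G31690 gave 3.15, below AT1G78450 at 4.27. Below 0 were AT4G23680 at -5.39, AT1G17960 at -5.58 ± 0.16 and M17 at -5.47 ± 0.16, with the sizes of the last pair uncertain because of dim levels in WT at 0 h and, for AT1G17960, in rdm4 at 3 h. The NRPB family had a median difference of -1.04 (adjusted p = 0.00426, and adjusted p = 0.439 with an estimated correlation). The root markers had a median of -1.96 over the same arrays (adjusted p = 0.00383, and adjusted p = 0.351 with an estimated correlation). The 9826 calls draw on the 3 h arrays, whose genotype difference ran opposite to that at 0 h.

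Probe sets of the mean 3 h response, 613 induced and 262 repressed at least 2-fold, had median differences of rdm4 minus WT of -0.03 (camera p = 0.422) and 0.27 (camera p = 2.95e-04, and p = 0.0925 with an estimated correlation). The median near 0 of the induced sets does not mean that their responses were alike. Their quartiles were -1.13 and 0.75, with 240 called larger and 246 called smaller in rdm4. These p-values were not adjusted over the sets tested. The repressed sets fell by a median of 1.51 in WT and 1.27 in rdm4.

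Over 48 h AT4G27280 had a difference of 5.70 ± 0.10 (adjusted p = 1.66e-11), AT5G52760 of 5.44 ± 0.20, AT3G48640 of 5.43 ± 0.16, AT1G66090 of 4.93 ± 0.13 and AT1G72900 of 4.80 ± 0.14, where the sizes for AT5G52760 and AT1G66090 are uncertain because of dim levels in rdm4 at 0 h. STZ fell by 1.25 ± 0.07 in WT and rose by 3.03 ± 0.07 in rdm4, a difference of 4.28 ± 0.09. In the CML family 6 of 7 differences were called above 0 (adjusted p = 1.01e-05, and adjusted p = 0.351 with an estimated correlation), and in the PUB family of ubiquitin ligases 5 of 9 were called above 0, with PUB24 at 1.66 ± 0.14, from a dim level in WT at 48 h (adjusted p = 0.0173, and adjusted p = 0.592 with an estimated correlation). In the PDF family 3 of 7 were called below 0 (adjusted p = 0.0288, and adjusted p = 0.427 with an estimated correlation). The call was lost when the dimmest 30% of probe sets were left out, although the median went from -0.41 to -0.48. AT4G30170 was at -2.74 ± 0.14 and M17, with its dim level in WT at 0 h, at -3.87 ± 0.16, and the root markers had a median of -1.37 over the same arrays (adjusted p = 0.00957, and adjusted p = 0.351 with an estimated correlation).

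COR15A and COR15B rose more in rdm4 over 48 h, by 0.91 ± 0.11 (adjusted p = 7.62e-05) and 0.39 ± 0.09, from lower levels at 0 h, and LTI30 was at 0.33 ± 0.11 (adjusted p = 0.0592). The 1296 probe sets induced at 48 h had a median difference of 0.0601 (camera p = 9.82e-04, and p = 0.0422 with an estimated correlation), and the 1103 repressed sets of -0.07 (camera p = 0.448). Quartiles of the induced sets were -0.42 and 0.71, with 466 called larger and 357 called smaller in rdm4. These p-values were not adjusted over the sets tested. In total 5053 probe sets were called, 2153 above 0 and 2900 below 0. At least 2-fold, the balance was the other way, with 620 above 0 and 302 below 0.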

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

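The tests of the sign change at 3 h and of the root markers were chosen after the results were seen, and the test of gene order was set out before its result was seen. Each result listed here was picked out because the genotypes' responses differed. They did so in 9826 probe sets at 3 h and 5053 at 48 h by the test of the difference itself. Probe sets repressed at 3 h had a median difference of 0.27 (camera p = 2.95e-04), which was lost with an estimated correlation (p = 0.0925), and those induced at 48 h of 0.0601 (camera p = 9.82e-04, and p = 0.0422 with an estimated correlation). These p-values were not adjusted over the sets tested, and the quartiles of the sets induced at 48 h were -0.42 and 0.71. Among lists, the COR genes differed by a median of 1.45, the root markers by -1.96 and the NRPB family by -1.04 at 3 h. With an estimated correlation these calls were lost, at adjusted p = 0.351, 0.351 and 0.439. At 48 h the root markers differed by -1.37, the CML family by 0.57, the PDF family by -0.41 and the PUB family by 0.50. With an estimated correlation these calls were lost too, at adjusted p = 0.351, 0.351, 0.427 and 0.592. The PDF call was also lost without the dimmest 30% of probe sets, where its median was -0.48.

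For single genes, the 3 h response in rdm4 minus that in WT was 6.999 for PDF1.2b, 4.75 for AT1G31690 (3.15 on its other probe set), 4.27 for AT1G78450, 3.48 for AT5G59670, 3.30 for AT3G21950, 2.62 for COR15A and 1.79 for COR15B. Below 0 were AT1G17960 at -5.58, M17 at -5.47, AT4G23680 at -5.39, XTH19 at -5.20 and AT4G11190 at -4.56. For the 48 h responses it was 5.70 for AT4G27280, 5.44 for AT5G52760, 5.43 for AT3G48640, 4.93 for AT1G66090, 4.80 for AT1G72900, 0.91 for COR15A and 0.39 for COR15B. Below 0 were M17 at -3.87, AT4G30170 at -2.74, AT2G28490 at -2.70, AT1G04560 at -2.61 and AT1G22440 at -2.50. The sizes for AT1G17960, M17, XTH19, AT5G59670, AT5G52760 and AT1G66090 are uncertain, since each uses a level among the dimmest 30% of a group's probe sets.

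A candidate explanation of the sign change at 3 h is an exchange of genotype labels between the 3 h arrays. Of the probe sets chosen at 0 h and 48 h that were called at 3 h, 97.3% of 75 went the opposite way, against 87.5% of 8 at 48 h and 92.9% of 14 at 0 h for probe sets chosen at the other times, and with no minimum size these shares lay further apart, at 97.0% of 2337, 69.1% of 230 and 86.1% of 512. Over those 81 the WT 3 h arrays were nearer the rdm4 mean for 91.4% and 92.6% and the rdm4 3 h arrays for 21.0% and 19.8%. A chamber or batch effect in 1 replicate is argued against by both replicates: the lower had the opposite sign for 92.6% of them. A batch effect shared by both replicates was not tested. Labels exchanged at both 0 h and 48 h would give the same values. A difference in RNA quality stays open, but the 3′ minus 5′ controls did not follow the sign change. That of GAPDH changed sides at 3 h and, unlike the genotype difference, did not change back at 48 h (-0.20 at 0 h, 0.12 at 3 h, 0.03 at 48 h). Those of actin (-0.06, -0.07, -0.005) and ubiquitin (-0.01, -0.03, 0.02) did not change sides at 3 h. A true reversal stays open too. The median genotype difference at 3 h was -0.998 of the median size at the other times, but no transcript that marks the genotype was analysed here. An exchange at 3 h would change the 3 h response of each genotype, their difference and the 3 h genotype comparison. An exchange at 0 h and 48 h would change both responses of each genotype and the difference of the 3 h responses. It would also turn the signs of the genotype comparisons at 0 h and 48 h and of the difference of the 48 h responses. Neither exchange would change the mean responses.

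Root markers were higher in rdm4 at 0 h, and root tissue in the leaf samples may account for this. All 3 named markers were called higher, among them the abundant PYK10, at a log2 level of 11.92 against 10.60 in WT. A change of these genes within the leaf predicts the same, so the explanations cannot be told apart with 3 markers, and the other 9 of the 12 on that list were not analysed here. AT5G17820 stood at 4.75, 8.03 and 7.05 in WT at 0, 3 and 48 h, and at 6.53, 6.49 and 7.15 in rdm4. It was thus lower in rdm4 at 3 h, and the same explanations are open for the WT responses at 3 h and 48 h. The genotype as a biological cause was not tested separately.

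Genes that differed at least 2-fold between the genotypes at both 0 h and 48 h might mark a chromosome segment that differs between the plant lines. Of the 39 named genes placed in chromosomal order, 3 pairs lay within 50 genes of each other, against a median of 3 in 10000 random sets (permutation p = 0.501). The prediction set out before had counted a value at or below that median against a segment, but random sets ran from 0 to 6 pairs at their 5th and 95th percentiles, so the test decided nothing with this few genes and the segment cannot be told apart from scattered differences. Whether the lines differ in accession, on which the labels conflict, was not tested.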

How the results depend on the processing

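Leaving out all 3 h arrays and the alternatives for the symbol families and the mean responses were added after the data were seen; the others were planned. Of 215 counts under alternatives, 204 stayed within 1.5 times the value reported, and only the 2-fold minimum moved them, by its own construction: to 1589 and 2533 for WT at 3 h and 48 h, 1182 and 2698 for rdm4, 434, 599 and 729 for rdm4 against WT at 0, 3 and 48 h, 2162 and 922 for the differences of responses at 3 h and 48 h, and 875 and 2399 for the mean responses. Centring each array on its median moved the share of higher calls by 11.8 percentage points for rdm4 against WT at 3 h, and by at most 6.9 points in either direction for the others. Without the 3 h arrays, the genotype comparisons at 0 h and 48 h gave 6309 and 7582 calls. The median difference of genes induced at 3 h, -0.03, changed sign with repeated quantile normalization (0.0006) and with median centring (0.0437), and ranged from -0.0276 to 0.0504 when single arrays were left out; the cause was not tested. The median of plastid-encoded genes in rdm4 against WT at 0 h ranged from -0.6437 to 0.0741 with single arrays left out. Of 772 list results 748 kept their call, 23 lost it and 1 changed sign, and of 3994 gene results 3990 were the same. The replicate numbers showed no pairing common to all groups: in 4 of 15 pairs of groups the replicate deviations correlated above 0.1 (range -0.15 to 0.27). Pairing between some groups stays possible. With a replicate block, the calls numbered 10688 for WT at 3 h and 5036 for the difference of the 48 h responses, and the block moved no count by over 1.5 times and changed no call of a reported gene or list. RDM4 levels gave no value because its probe set is unnamed here. Leaving out the dimmest 30% of probe sets ended 11 list calls without changing the sign of their medians, and background signal was not measured apart from this.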

Other observations

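The fixed lists too small to test had 19 named members, of which 11 rose, 6 fell and 2 were not called in WT at 48 h, and 10 rose, 5 fell and 4 were not called in rdm4. Among those not called in either were SIZ1 at -0.0003 ± 0.07 in WT and -0.13 ± 0.07 in rdm4, and ATHSP22.0 at 0.06 ± 0.08 and 0.18 ± 0.08. The other probe set of SIZ1 was at 0.23 ± 0.15 and 0.01 ± 0.15 and was not called. GR1, a glutathione reductase gene, rose by 1.74 ± 0.08 in WT and 1.26 ± 0.08 in rdm4, and EIN3, a factor of ethylene signalling, fell by 0.63 ± 0.07 and 0.60 ± 0.07. The ribosome biogenesis gene AT3G05060 rose by 1.66 ± 0.09 and 0.93 ± 0.09, and the DNA glycosylase gene DME fell by 1.07 ± 0.09 and 0.64 ± 0.09. The other probe sets of DME moved less, at -0.02 and -0.50 in WT and at -0.19 and -0.19 in rdm4. Of these changes only the -0.50 in WT was called. WRKY53, a factor gene of the WRKY family, fell by 0.68 ± 0.11 in WT and rose by 3.06 ± 0.11 in rdm4, a difference of 3.73 ± 0.16 (limma, adjusted p = 8.79e-09), and was chosen after its values were seen. Its level was dim in WT at 48 h and in rdm4 at 0 h, so these sizes are uncertain. ATSPS4F, a sucrose phosphate synthase gene, rose by 0.82 ± 0.07 in WT and 0.45 ± 0.07 in rdm4.

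Of the 100 probe sets with the largest called changes, those without a single gene name numbered 60 for WT at 3 h, 64 for WT at 48 h and 52 for rdm4 against WT at 0 h.

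The following fit was chosen after the sign change at 3 h was seen. In a model of time plus genotype over all 12 arrays, the mean residual sum of squares per probe set was 0.423 with the labels as given, 0.241 with the genotype labels exchanged at 3 h, 0.361 with those at 0 h and 0.388 with those at 48 h. A true reversal at 3 h would lower the residual in the same way, so this fit cannot separate it from an exchange of labels. No comparison was made with exchanged labels.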
